A study of Homo sapiens with 12 samples.

How the data were processed

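RNA was measured in 12 libraries of T47D cells, an estrogen receptor-positive breast cancer line, made with an inducible short hairpin RNA against PSMD2, a subunit of the 19S regulatory particle of the proteasome. Per the labels, the Lo19S state was induced with 0.2 µg/ml doxycycline for 3 days, followed by 24 h without it, and control cells were left uninduced. Cells of each state then received the proteasome inhibitor bortezomib at 20 nM or its solvent DMSO for 16 h, which gives 4 groups of 3 libraries. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded polyA kit. The deposited files hold whole-number counts of reads per gene, 1 file per library, without normalization. Per the submitters' processing notes, the tools were STAR 2.5.4b and featureCounts 1.6.1 and the genome build was GRCh37. The strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of near-identical paralogs such as HSPA1A and HSPA1B, and of overlapping or antisense genes, are uncertain.

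Each file held 57773 genes by Ensembl identifier, all of them naming a gene, and 51996 identifiers were matched to a symbol. Library totals ran from 7376597 to 15003480 counts. At this depth a count of 0 in a library allows up to 3 counts, and floors and counting intervals given here cover counting error only, since reads without molecular identifiers are not independent molecules. The reference annotation at hand, GENCODE release 29, was made for another build than the counts, so it was used only for biotypes and for the GC content of transcripts, and no coordinates are given.

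Groups were taken from the sample labels. Counts were filtered with filterByExpr by group, which left 14714 genes, scaled with trimmed-mean-of-M-values (TMM) factors and fitted with a negative binomial model with 1 coefficient per group over all 12 libraries, using the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The comparisons, 5 in all, were Lo19S against control under DMSO, bortezomib against DMSO in control cells, bortezomib against DMSO in Lo19S cells, Lo19S against control under bortezomib, and the difference of the bortezomib responses, Lo19S minus control. Every adjusted p of a gene comes from this edgeR test with Benjamini-Hochberg adjustment over the genes tested in a comparison, and a gene was called at an adjusted p below 0.05. Levels are TMM-scaled CPM (counts scaled to a common library size) with their SD over 3 libraries, and log2 fold changes come from the fit. Their standard errors (SE) were computed as the absolute log2 fold change over the square root of the test's F statistic. They are approximate, above all for large changes and for genes with few counts. For a gene at 0 counts in a group, the fold was computed against 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio is given with its exact 95% counting interval.

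There were 35 gene lists with 684 genes, of which 680 were found in the files under their symbol and 620 were measured. They are the 19S regulatory particle subunits other than PSMD2, the 20S core particle subunits, proteasome assembly factors and activators, ubiquitin with p97 and shuttle factors, cytosolic heat shock proteins and co-chaperones, the endoplasmic reticulum unfolded protein response, ATF4 and integrated stress response targets, cytosolic aminoacyl-tRNA synthetases, NRF2 targets, metallothioneins, and glutathione transferases with peroxidases and peroxiredoxins. The lists of metabolism are nuclear-encoded oxidative phosphorylation subunits, mitochondrial-DNA-encoded subunits, mitochondrial ribosomal proteins, the tricarboxylic acid cycle, protein lipoylation with iron-sulfur cluster assembly, glycolysis, fatty acid oxidation, and cholesterol synthesis. Further lists are estrogen receptor targets, luminal markers, basal and mesenchymal markers, DNA replication, mitosis, p53 targets, pro-apoptotic BCL2 family members and death receptors, NF-kappaB targets, interferon-stimulated genes, immediate early and AP-1 genes, autophagy and lysosome, cytosolic ribosomal proteins and hypoxia response. Markers of fibroblasts, leukocytes and endothelial cells stand for other cell types. Despite its name, the cytosolic heat shock list also holds HSPD1 and HSPE1, which encode mitochondrial chaperones, and SERPINH1, of the endoplasmic reticulum. Each list with at least 4 measured members, 31 in all, was tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Each test was repeated with a correlation estimated per list and with fry. Members were also counted with p-values adjusted over the list alone.

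The size of the bortezomib response in Lo19S cells relative to control cells was the slope through 0, by total least squares, of the log2 fold changes over the genes called for the average response of both states, with an error from leaving out each library in turn. Library measures were compared with 2-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

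Genes named for a comparison are a panel named whatever its values (PSMD2, HSPA1A, HSPA1B, DNAJB1, HMOX1, DDIT3, ATF4, FDX1, ESR1, PGR and CDKN1A), the 5 protein-coding genes with the largest rise and the 5 with the largest fall, and members of the lists. The first kind of choice had no threshold, while the largest changes were taken among called genes with at least 5 CPM in the higher group and, for comparisons of 2 groups, no overlap between the libraries of the groups. Up to 4 members of a list are named, those with the largest change in the direction most called members moved, then the called member with the largest change the other way. Some genes that meet this rule are not reported here. These 35 lists, the groups, the tests of genes and lists, this rule and the alternatives, other than those named below as added, were fixed before the data were examined. Other lists and tests were chosen later, as said where they are reported.

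Alternatives to these choices were RLE factors, upper-quartile factors and library totals in place of TMM, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, leaving out each of the 12 libraries, and for the response ratio a different choice of genes. Each fit without a library repeated the filter, the scaling and the estimate of spread. Offsets from the GC content of transcripts and thinning of every library to the smallest total were added after seeing the data. The scripts were tested on simulated counts with 200 genes changed by a known fold. For Lo19S against control under DMSO, 51% of genes changed by 1.25-fold, 82.5% changed by 1.5-fold and 84% changed by 2-fold were recovered, and for the difference of responses 26%, 60% and 69%. Calls on unchanged genes made up 8.93%, 4.07% and 8.2% of all calls in the former and 8.77%, 4.76% and 6.12% in the latter. Coordinates, sequences and isoforms were left out because the files give counts per gene.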

Results

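Polyadenylated RNA of T47D breast cancer cells was counted per gene in 12 libraries. Control cells and cells in the Lo19S state, made by induced knockdown of the 19S proteasome subunit PSMD2, were each given DMSO or bortezomib for 16 h, with 3 libraries in each of the 4 groups. Library totals were 11898216, 9654402 and 9651434 counts for control cells with DMSO, 11166173, 10295363 and 8291365 for Lo19S cells with DMSO, 9557627, 10524265 and 9817390 for control cells with bortezomib, and 9100334, 7376597 and 15003480 for Lo19S cells with bortezomib. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Control DMSO replicate 3 stood apart from its group, with a chi-square per degree of freedom of 3.64 and 3.99 against the other replicates, where all other replicate pairs lay between 1.15 and 1.90.

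PSMD2, the knockdown target, was at 408.1, 392 and 417.3 scaled counts (CPM) in the control DMSO libraries and at 182.9, 189.2 and 183.9 CPM in the Lo19S DMSO libraries. With bortezomib it was at 1509, 1510 and 1528 CPM in control cells and at 540.6, 545.8 and 539.6 CPM in Lo19S cells. PSMD2 was 2.19-fold lower in the Lo19S state under DMSO (log2 fold change -1.13, SE 0.035, adjusted p = 6.27e-30) and lower again under bortezomib (log2 fold change -1.48, SE 0.033). Bortezomib raised PSMD2 in both states, by 1.90 log2 units (SE 0.033) in control cells and 1.55 (SE 0.035) in Lo19S cells, and these responses differed by -0.35 (SE 0.047, adjusted p = 7.1e-08). The first 3 components of the gene levels held 84.1%, 5.9% and 2.1% of the variance.

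**Figure D1:**
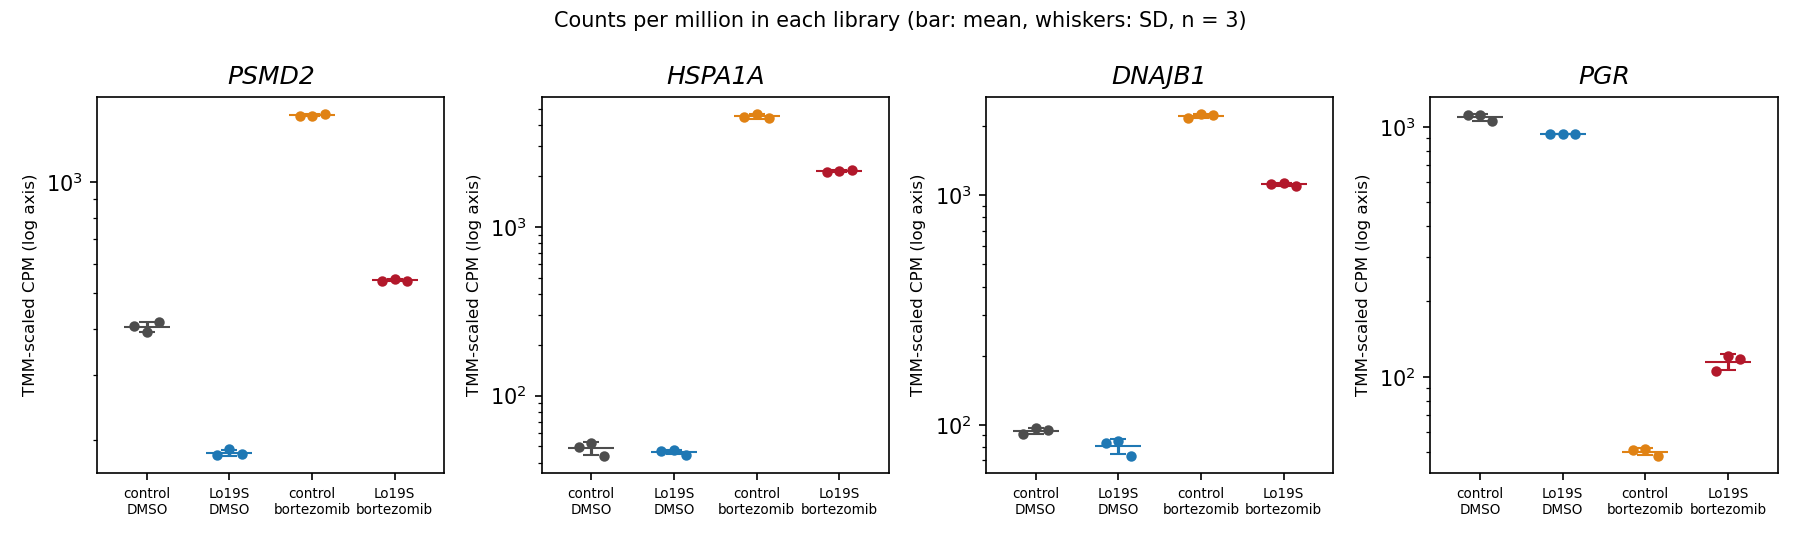
TMM-scaled CPM of PSMD2, HSPA1A, DNAJB1 and PGR on a log axis, 1 point per library, with the mean as a bar and the SD as whiskers (n = 3 per group). PSMD2 averaged 405.8 CPM in control and 185.3 CPM in Lo19S cells with DMSO, and HSPA1A 4518 CPM in control and 2141 CPM in Lo19S cells with bortezomib.

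Lo19S cells were compared with control cells under DMSO to describe the state itself. Genes of the proteasome other than PSMD2 were higher in the Lo19S state, and genes of DNA replication and mitosis were lower. Of 17 measured 19S subunits 16 rose, led by ADRM1 (log2 fold change 0.83, SE 0.043), PSMD3 (0.79, SE 0.038) and PSMD14 (0.77), with a median of 0.61 (camera adjusted p = 1.05e-30). All 13 measured subunits of the 20S core, the proteolytic chamber, rose as well, with a median of 0.62 (adjusted p = 1.19e-27), among them PSMB6 (0.87, SE 0.046), PSMA1 (0.81) and PSMB2 (0.79). All 25 mitosis genes fell, with a median of -0.44 (adjusted p = 1.1e-33), for example MKI67, a proliferation marker (-0.54, SE 0.036), CENPF (-0.54, SE 0.045) and CENPA. Of 25 replication genes 24 fell and 25 when adjusted over the list alone (median -0.35, adjusted p = 1.81e-24). GINS2 changed by -0.51 (SE 0.050), MCM10 by -0.50 (SE 0.054) and CHAF1A by -0.48.

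In all, 3628 of 14714 genes differed under DMSO, 1720 higher and 1908 lower in Lo19S cells, with 180 at least 2-fold higher and 35 at least 2-fold lower. The largest rises were those of NAP1L2, a nucleosome assembly protein (20.1-fold, from 0.287 to 5.97 CPM, log2 4.33, SE 0.307, adjusted p = 4e-16), NLRP1, an inflammasome sensor (7.90-fold, from 6.01 to 47.8 CPM, log2 2.98, SE 0.093), DYSF, which encodes the membrane repair protein dysferlin (7.88-fold), MAP1A, a microtubule-associated protein (7.42-fold), and KIAA0319 (6.90-fold). The largest falls were those of CNN1, the actin-binding calponin (log2 -2.78, SE 0.244, adjusted p = 4.86e-13), CCN2, a matricellular growth factor (-1.87, SE 0.176), ACTA2, smooth muscle actin (-1.84, SE 0.060, from 173.5 to 48.6 CPM), the interferon-inducible GTPase GBP1 (-1.45) and CHST3 (-1.18).

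Antioxidant genes rose in the Lo19S state. Of 19 NRF2 targets 13 rose (median 0.47, or 0.43 with AKR1B10, at 0 counts in control cells, set to its bound, adjusted p = 2.38e-12), including the cystine transporter SLC7A11 (1.13, SE 0.071) and the heme oxygenase HMOX1 (0.89, SE 0.117). Among glutathione transferases, peroxidases and peroxiredoxins 11 of 19 rose and 2 fell, or 12 and 3 when adjusted over the list alone (median 0.18, adjusted p = 1.97e-07). GPX3 changed by 2.06 (SE 0.049) and PRDX1 by 0.61. Of 18 genes of ubiquitin, p97 and shuttle factors 10 rose and 2 fell, 11 and 4 when adjusted over the list alone (median 0.18, adjusted p = 5.7e-08). UCHL1, a deubiquitinase, changed by 2.25 (SE 0.106) and the autophagy receptor SQSTM1 by 0.76 (SE 0.033). Autophagy and lysosome genes shifted upward, 7 of 23 rising and 1 falling (median 0.06, adjusted p = 0.000101). GABARAPL1 changed by 0.96 and the lysosomal protease CTSD by 0.52. Estrogen receptor targets fell, 13 of 19 against 1 that rose (median -0.21, adjusted p = 7.73e-07), including PDZK1 (-0.92, SE 0.204) and TFF3 (-0.63), and the receptor gene ESR1 (-0.28, SE 0.039) and its target PGR (-0.23, SE 0.034) fell too. Of 18 genes of the endoplasmic reticulum unfolded protein response 10 fell, and 12 when adjusted over the list alone (median -0.15, adjusted p = 3.3e-05). The chaperones HSPA5 and CALR changed by -0.27 and -0.26.

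Genes of the heat shock list did not rise as a group under DMSO: 13 of 24 fell and 2 rose, 14 and 2 when adjusted over the list alone (median -0.14, camera adjusted p = 0.000208, adjusted p = 0.20 with an estimated correlation). HSPH1 (-0.30, SE 0.042), the mitochondrial HSPD1 (-0.29) and FKBP4 (-0.26) fell, DNAJB1 fell by 0.22, and BAG3 rose by 0.35. HSPA1A and HSPA1B, whose near-identical sequences make their separate counts uncertain, differed by -0.07 each (adjusted p = 0.414 and 0.449). ATF4 targets fell in 6 of 20 cases and rose in 1 (median -0.14, adjusted p = 0.0191, adjusted p = 0.18 with an estimated correlation and 0.0509 without control DMSO replicate 3). STC2 changed by -0.45 and SLC3A2 by -0.29. ATF4 itself (-0.02, adjusted p = 0.817) and DDIT3, a pro-apoptotic transcription factor (0.12, adjusted p = 0.303), did not pass the test, nor did CDKN1A, the cell cycle inhibitor p21 (-0.01, adjusted p = 0.95), or FDX1, a mitochondrial ferredoxin (0.03, adjusted p = 0.848).

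Mitochondrial-DNA-encoded genes were called higher, 4 of 13 rising and 5 when adjusted over the list alone (median 0.05, adjusted p = 0.00362, adjusted p = 0.37 with an estimated correlation and 0.082 with fry). MT-CO1 changed by 0.16. Glycolysis genes rose in 7 of 18 cases and fell in 3, 8 and 3 when adjusted over the list alone (median 0.10, adjusted p = 0.0329), with ALDOA at 0.48 and GPI at 0.40, a call lost with adjusted p = 0.29 with an estimated correlation and with 0.0573 without control DMSO replicate 1. NF-kappaB targets fell in 4 of 15 cases (median -0.24, adjusted p = 0.0395, adjusted p = 0.10 with an estimated correlation), with IER3 at -0.53, and this call was lost without control DMSO replicate 3 (0.0595), Lo19S DMSO replicate 1 (0.0691) or Lo19S DMSO replicate 3 (0.0524). Luminal markers (3 of 18 rising and 6 falling, median -0.04, adjusted p = 0.096) were called without control DMSO replicate 1 (0.0264) and with fry (0.0046). Ribosomal proteins (1 of 42 rising, 0 when adjusted over the list alone, median 0.02, adjusted p = 0.417) were called without control DMSO replicate 3 (0.0349). Immediate early genes (3 of 19 rising and 7 falling, median -0.15, adjusted p = 0.0695) were called without control DMSO replicate 1 (0.0267) or 2 (0.0305) or Lo19S DMSO replicate 2 (0.0252), and with fry (0.009).

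Further lists did not pass the camera test under DMSO. With fry, which compares a list with no other genes, assembly factors (adjusted p = 0.007) and fatty acid oxidation (0.00015) were called upward. Cholesterol synthesis (9.3e-05), BCL2 family genes (0.02) and mitochondrial ribosomal proteins (0.049) were called downward with fry. Proteasome assembly factors and activators had 2 of 12 rising, the maturation factor POMP at 0.47 and the activator PSME4 at 0.35, and 1 falling (adjusted p = 0.307). Among tRNA synthetases 2 of 14 rose and 1 fell (0.525), among nuclear-encoded oxidative phosphorylation genes 6 of 42 rose and 1 fell (0.242), and among mitochondrial ribosomal proteins 2 of 30 rose and 3 fell, 2 and 2 when adjusted over the list alone (0.308). The tricarboxylic acid cycle had 4 of 17 rising and 3 falling, 6 and 4 over the list alone (0.551), and fatty acid oxidation 5 of 19 and 1, 6 and 2 over the list alone (0.157). ACADVL changed by 0.63. Lipoylation and iron-sulfur genes had 5 of 23 falling, 6 over the list alone (median -0.01 and 0.01 with library totals, 0.404), and cholesterol synthesis 2 of 21 rising and 4 falling, 2 and 5 over the list alone (median 0 and 0.02 with library totals, mean -0.03, 0.272). Basal markers moved in 2 of 10 cases each way (0.766), p53 targets in 1 of 19 upward and 2 downward (median -0.02 and 0 with library totals, 0.815), BCL2 family genes in 3 of 13 downward (0.432) and hypoxia genes in 3 of 17 each way, 4 and 3 over the list alone (0.676). Interferon-stimulated genes had 4 of 23 rising, with IFI44 at 1.74 and IFIT2 at 1.53, and 2 falling, with OAS2 at -0.82, and their median of -0.11 and mean of 0.05 differed in sign (0.96). Lists too small to test held 1 of 2 metallothioneins falling, fibroblast markers with 1 of 3 rising and 1 falling, 0 of 1 leukocyte markers changing and 1 of 1 endothelial markers falling. Summed markers of fibroblasts, leukocytes and endothelial cells reached at most 65.7, 4.35 and 7.77 CPM in any library.

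The counts under DMSO come from the edgeR test, in which the median SE of a log2 fold change was 0.084. Of 31 lists tested, 8 were called higher and 7 lower, and 10 of these calls held with an estimated correlation. Doxycycline was given to both Lo19S groups and to neither control group, so its own effect and that of the hairpin are not separate here, and without control DMSO replicate 3 the count of genes was 4603.

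Bortezomib was compared with DMSO in control cells to describe the response of uninduced cells. Heat shock genes rose strongly: all 24 members were higher (median log2 fold change 2.28, camera adjusted p = 1.33e-18). HSPA1A rose from 48.7 to 4518 CPM (log2 6.53, SE 0.045) and HSPA1B by 6.66 (SE 0.049), both inducible HSP70 genes whose reads can be confused. DNAJB1, an HSP40 co-chaperone, rose from 94.2 to 2220 CPM (4.56, SE 0.041), the small heat shock gene CRYAB by 7.65 (SE 0.125) and HSPA6, which is on no list, from 0.735 to 388.3 CPM (9.05, SE 0.103). Genes of the proteasome rose together, 16 of 17 for the 19S particle (median 1.254, adjusted p = 1.79e-09) and 13 of 13 for the 20S core (median 1.18, adjusted p = 2.61e-07), including PSMC1 (2.42, SE 0.172), PSMD12 (1.80, SE 0.043), PSMA6 (1.59) and PSMA1 (1.46, SE 0.064).

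Further stress lists rose in control cells. Ubiquitin, p97 and shuttle factors rose in 17 of 18 cases (median 1.63, adjusted p = 2.05e-08, and 14 rising and 3 falling with library totals). ZFAND2A changed by 4.65 and SQSTM1 by 2.81. The unfolded protein response list had 17 of 18 rising (1.31, adjusted p = 6.19e-09). HSPA5 changed by 3.63 and HERPUD1 by 3.01, against XBP1, its transcription factor, by -2.06. ATF4 targets rose in 17 of 20 cases and fell in 2 (1.72, adjusted p = 4.29e-07). GDF15 changed by 5.56, the phosphatase subunit PPP1R15A by 4.63, DDIT3 by 4.02 (SE 0.055) and ATF4 by 1.33 (SE 0.043). NRF2 targets rose in 18 of 19 cases (2.59, adjusted p = 2.61e-07). SLC7A11 changed by 4.82 and HMOX1 by 3.64 (SE 0.085). Of 14 tRNA synthetases 12 rose and 2 fell (0.82, adjusted p = 4.04e-05), with WARS1 at 1.47, and of 23 autophagy and lysosome genes 20 rose and 2 fell (0.63, adjusted p = 2.62e-05, and 12 and 5 with library totals), with MAP1LC3B at 3.33 and GABARAPL1 at 3.39. NF-kappaB targets rose in 11 of 15 cases and fell in 4 (0.99, adjusted p = 0.00509), with the chemokine CXCL8 at a count ratio of 443 (95% counting interval 151 to 2150) and TNF at 3.76. Hypoxia genes rose in 12 of 17 cases and fell in 3 (1.10, adjusted p = 0.00104). NDRG1 changed by 3.46 and P4HA2 by 2.32.

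Cell cycle and estrogen response genes fell with bortezomib in control cells. All 25 mitosis genes fell (median -1.89, adjusted p = 1.5e-13), with the mitotic kinase PLK1 at -3.70 (SE 0.076), KIF20A at -3.14 and CDC20 at -2.69, while CDKN1A rose by 3.40 (SE 0.054). Estrogen receptor targets fell in 17 of 19 cases (-2.06, adjusted p = 5.16e-07). PGR, the progesterone receptor, fell from 1094 to 50.2 CPM (-4.45, SE 0.046), CXCL12 by 5.01 and ESR1 by 3.12 (SE 0.054), and AREG, an EGF receptor ligand, moved the other way (3.16). Replication genes fell in 17 of 25 cases and rose in 5, 17 and 6 when adjusted over the list alone and 22 and 2 with library totals (-0.39, adjusted p = 0.00661, adjusted p = 0.16 with an estimated correlation). GINS1 changed by -2.15 and CCNE1 by 1.19. Luminal markers fell in 12 of 18 cases and rose in 5 (-1.91, adjusted p = 0.00562, adjusted p = 0.11 with an estimated correlation). SPDEF changed by -3.26, MUC1 by -3.12 and CLDN4 by 1.84. Basal markers rose in 8 of 10 cases and fell in 2 (1.51, adjusted p = 0.0136, adjusted p = 0.10 with an estimated correlation). CD44 changed by 2.76 and the mesenchymal filament VIM by -2.72.

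Immediate early genes rose in 14 of 19 cases and fell in 3, 15 and 3 when adjusted over the list alone (0.99, adjusted p = 0.00269, adjusted p = 0.13 with an estimated correlation). FOSL1 changed by 7.55 and DUSP1 by 5.22. Ribosomal protein genes rose in 39 of 42 cases (0.39, adjusted p = 9.84e-08, adjusted p = 0.18 with an estimated correlation). With library totals 11 of them rose and 10 fell (median 0.005). RPS20 changed by 0.69. Of 13 mitochondrial-DNA-encoded genes 12 rose (0.44, adjusted p = 3.82e-05, adjusted p = 0.16 with an estimated correlation), with MT-CO1 at 0.75, and with library totals 5 rose and 1 fell (median 0.053). Nuclear-encoded oxidative phosphorylation genes fell in 25 of 42 cases and rose in 9, 36 and 0 with library totals (-0.24, adjusted p = 0.0121, adjusted p = 0.25 with an estimated correlation), with NDUFB10 at -1.65. Fatty acid oxidation genes fell in 13 of 19 cases and rose in 2 (-0.32, adjusted p = 0.0282, adjusted p = 0.076 with an estimated correlation). CPT1A, which brings fatty acids into mitochondria, changed by -2.06 and ACADVL by 0.71.

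By fitted log2 fold change, which for genes at 0 counts in a group depends on the prior count, the 5 genes of control cells taken by the rule for rises were CALCA, the calcitonin gene (at least 281-fold), CYP4F11 (at least 92.9-fold), CCL26 (at least 90.1-fold), the keratin gene KRT6A (log2 9.33, SE 0.188) and HSPA6. Those taken for falls were RBBP8NL (at least 141-fold), the transcription factor GATA4 (at least 59.1-fold), the chemokine CCL28 (at least 48.1-fold), MAP2K6 (a count ratio of 154, 95% counting interval 27.3 to 6100) and MYRFL (82.4, 28 to 402). FDX1 rose by 0.64 (SE 0.091) and PMAIP1, a pro-apoptotic BCL2 family gene, by 3.67, while BMF of the same family fell by 4.26. Lists not called were assembly factors (adjusted p = 0.657), mitochondrial ribosomal proteins (0.696), the tricarboxylic acid cycle (0.497), lipoylation genes (0.548), glycolysis (0.965), cholesterol synthesis (0.696), glutathione genes (0.965), p53 targets (0.246), BCL2 family genes (0.0755) and interferon-stimulated genes (0.608).

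In control cells 11976 genes differed, 5761 higher (48.1%) and 6215 lower, with 2131 at least 2-fold higher and 3251 at least 2-fold lower and a median SE of 0.091. Of the lists, 15 were called higher and 6 lower, and 13 calls held with an estimated correlation. The 10 most abundant genes took 10.8% of counts (SD 0.0586) against 5.01% (SD 0.0808) with DMSO (exact permutation p = 0.1, the smallest these groups allow, 0.222 adjusted over 20 tests), and all changes are relative to TMM scaling. Scaled by library totals alone, the median of all genes was -0.424 (-0.043 with TMM) and 30.5% of the calls were higher.

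The same comparison in Lo19S cells gave the response of the state. All 24 heat shock genes rose (median 1.85, camera adjusted p = 5.68e-18). HSPA1A changed by 5.52 (SE 0.045), HSPA1B by 5.56 (SE 0.048), CRYAB by 4.83 (SE 0.174) and DNAJB1 by 3.79 (SE 0.041). Proteasome genes rose again, 16 of 17 of the 19S particle (0.78, adjusted p = 2.69e-08) and 13 of 13 of the 20S core (0.67, adjusted p = 7.17e-06, adjusted p = 0.058 with an estimated correlation). PSMC1 changed by 1.80, PSMC6 by 1.33 and PSMA6 by 1.07. All 20 ATF4 targets rose (1.80, adjusted p = 8.83e-11), led by GDF15 (5.60), DDIT3 (4.27, SE 0.054) and ATF3 (3.82), and ATF4 itself rose by 1.10. PLK1 (-2.51), KIF20A (-2.44), CDC20 (-2.10) and the other mitosis genes fell, 25 of 25 in all (-1.40, adjusted p = 4.65e-13).

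Further stress lists rose in Lo19S cells. Unfolded protein response genes rose in 17 of 18 cases (1.33, adjusted p = 5.34e-10), with HSPA5 at 3.99 and HERPUD1 at 2.77, NRF2 targets in 18 of 19 (1.90, adjusted p = 3.78e-07), with SLC7A11 at 3.94 and HMOX1 at 3.61, and ubiquitin and shuttle factors in 15 of 18 (1.04, adjusted p = 2.87e-08, and 13 rising and 4 falling with library totals), with ZFAND2A at 3.31. Among tRNA synthetases 12 of 14 rose and 1 fell (0.94, adjusted p = 3.78e-07), with WARS1 at 1.66, and among autophagy genes 19 of 23 rose and 2 fell, 20 and 2 when adjusted over the list alone (0.61, adjusted p = 8.11e-06, and 14 and 3 with library totals), with MAP1LC3B at 2.55. Hypoxia genes rose in 12 of 17 cases and fell in 2 (0.90, adjusted p = 0.000265), with NDRG1 at 2.44, and NF-kappaB targets in 11 of 15 and 2 (1.598, adjusted p = 0.00206), with TNF at 3.62. Immediate early genes rose in 12 of 19 cases and fell in 3 (0.81, adjusted p = 0.00206, adjusted p = 0.13 with an estimated correlation). FOSL1 changed by 6.18 and DUSP1 by 4.07. CDKN1A rose by 2.99 (SE 0.055) and FDX1 by 0.40 (SE 0.092), a call that ended with library totals (0.12) or with GC offsets (0.14).

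Estrogen receptor targets fell in 15 of 19 cases and rose in 3 (-1.89, adjusted p = 2.49e-06). CXCL12 changed by -5.08, MYB by -4.17 and PGR by -3.03 (SE 0.041), and ESR1 fell by 2.41 (SE 0.051). Luminal markers fell in 12 of 18 cases and rose in 6 (-1.17, adjusted p = 0.00946, adjusted p = 0.12 with an estimated correlation), with SPDEF at -3.16 and CLDN4 at 1.59, and replication genes fell in 15 of 25 and rose in 4, 21 and 2 with library totals (-0.48, adjusted p = 0.00266, adjusted p = 0.14 with an estimated correlation). Basal markers rose in 6 of 10 cases and fell in 2 (1.14, adjusted p = 0.0415, adjusted p = 0.14 with an estimated correlation). This call was lost without control DMSO replicate 2 (0.0918) or 3 (0.0874), Lo19S DMSO replicate 2 (0.0999) or 3 (0.089), control bortezomib replicate 1 (0.0902), 2 (0.0901) or 3 (0.0901), and Lo19S bortezomib replicate 1 (0.0629), 2 (0.0805) or 3 (0.085). Control libraries are not part of this comparison, and each such fit repeated the filter. These losses thus need not trace to the library left out. Oxidative phosphorylation genes fell in 25 of 42 cases and rose in 9, 33 and 0 with library totals (-0.17, adjusted p = 0.0248, adjusted p = 0.31 with an estimated correlation), and mitochondrial-DNA-encoded genes rose in 11 of 13 and fell in 1 (2 and 4 with library totals, median 0.25 and -0.04 with library totals, adjusted p = 0.0023, adjusted p = 0.30 with an estimated correlation).

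The largest fitted rises of Lo19S cells were those of CXCL8 (count ratio 266, 95% counting interval 73.2 to 2200), CYP4F11 (203, 36 to 8060), HSPA6 (log2 6.70, SE 0.135), the interleukin-33 receptor gene IL1RL1 (115, 31.5 to 959) and FOSL1 (SE 0.126). The largest fitted falls were those of GATA4 (at least 60.4-fold), SAMD11 (-5.60, SE 0.288), KLHDC7A (-5.60, SE 0.231), RANBP3L (-5.58, SE 0.351) and FREM2 (-5.35, SE 0.203). Ribosomal protein genes rose in 20 of 42 cases and fell in 5 (1 and 29 with library totals, median 0.09 and -0.20 with library totals, adjusted p = 0.115), a list called without Lo19S bortezomib replicate 3 (0.0329). Other lists not called were assembly factors (adjusted p = 0.313), mitochondrial ribosomal proteins (0.403), the tricarboxylic acid cycle (0.666), lipoylation genes (0.627), glycolysis (0.853), fatty acid oxidation (0.295) and cholesterol synthesis (0.0765). The same held for glutathione genes (0.627), p53 targets (0.102), BCL2 family genes (0.149) and interferon-stimulated genes (0.627).

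Lo19S cells had 11408 genes that differed with bortezomib, 5561 higher (48.7%) and 5847 lower, with 1510 at least 2-fold higher and 2725 at least 2-fold lower and a median SE of 0.088. Of the lists, 14 were called higher and 5 lower, and 12 calls held with an estimated correlation. Of genes higher with bortezomib, 4997 were higher in both states (2177.3 if the lists of the states were independent), and of genes lower 5346 were (2469.7 if independent), from comparisons that share no library. With library totals the median of all genes was -0.31 (-0.022 with TMM) and 32.0% of the calls were higher.

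**Figure D2:**
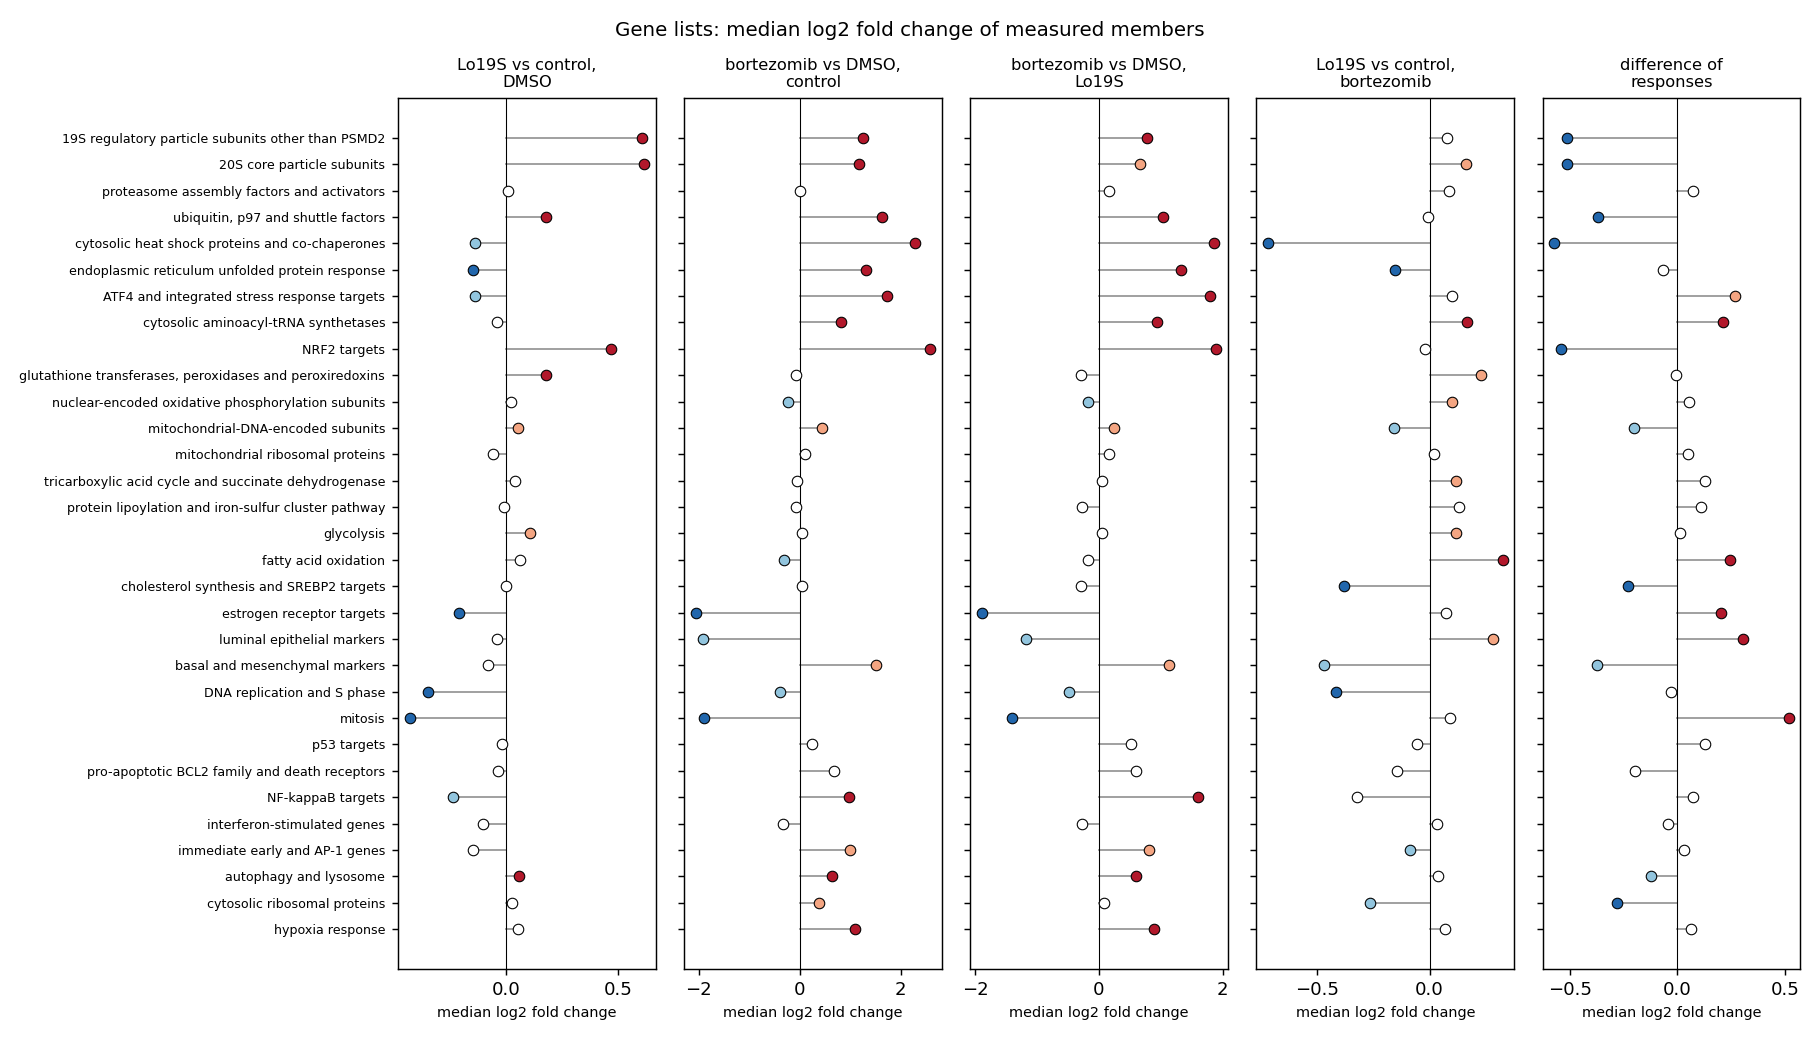
Median log2 fold change of the members of each of the 31 tested gene lists in each of the 5 comparisons. Dark symbols mark lists called with the preset and with an estimated correlation, pale symbols those called with the preset correlation only, and white symbols those not called, and the heat shock median was 2.28 and 1.85 with bortezomib and -0.14 in Lo19S cells under DMSO.

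Lo19S and control cells were compared under bortezomib to ask how the states differed during proteasome inhibition. Every heat shock gene was lower in the Lo19S state, 24 of 24 (median -0.72, camera adjusted p = 9.56e-43), among them CRYAB (-2.55, SE 0.069), the co-chaperone BAG3 (-1.61, SE 0.034), SERPINH1, a collagen chaperone (-1.48, SE 0.037), HSPA1A (-1.08, SE 0.033), HSPA1B (-1.17, SE 0.036) and DNAJB1 (-0.99, SE 0.034). Fatty acid oxidation genes were higher in 12 of 19 cases (0.33, adjusted p = 7.94e-05). CPT1A changed by 0.76 (SE 0.053) and SLC25A20 by 0.65. The tRNA synthetases were higher in 11 of 14 cases and lower in 1 (0.17, adjusted p = 7.41e-05). AARS1 changed by 0.40 and GARS1 by 0.38. Replication genes were lower in 22 of 25 cases and higher in 2 (-0.42, adjusted p = 5e-10), with the cyclins CCNE2 at -0.91 (SE 0.053) and CCNE1 at -0.61, against RFC4 at 0.42. Cholesterol synthesis genes were lower in 12 of 21 cases and higher in 1, 10 and 5 with library totals (-0.38 and -0.27 with library totals, adjusted p = 0.000146). HMGCS1 changed by -0.62.

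Unfolded protein response genes were lower in 11 of 18 cases and higher in 3, 8 and 4 with library totals (-0.15 and -0.04 with library totals, adjusted p = 0.000853). DNAJB9 changed by -0.54 and XBP1 by 0.41. PGR (1.19, SE 0.053), GREB1, another estrogen receptor target (1.15), and ESR1 (0.43, SE 0.070) were higher, and luminal markers were higher in 10 of 18 cases and lower in 2 (0.28, adjusted p = 0.000491, adjusted p = 0.07 with an estimated correlation). GATA3 changed by 1.2, AGR2 by 0.97 and KRT18 by -0.33. Basal markers were lower in 6 of 10 cases (-0.47, adjusted p = 0.00178, adjusted p = 0.07 with an estimated correlation), with FN1, fibronectin, at -0.56, and ribosomal proteins were lower in 41 of 42, 30 with library totals (-0.27, adjusted p = 7.94e-20, adjusted p = 0.07 with an estimated correlation), with RPS19 at -0.44. Glutathione genes were higher in 13 of 19 cases and lower in 1 (0.23, adjusted p = 0.000923, adjusted p = 0.16 with an estimated correlation). MGST1 changed by 0.46. Mitochondrial-DNA-encoded genes were lower in 9 of 13 cases, 5 with library totals (-0.16, adjusted p = 3.77e-06, adjusted p = 0.17 with an estimated correlation). MT-ND2 changed by -0.31. The 20S core was higher in 7 of 13 cases (0.16, adjusted p = 0.0093, adjusted p = 0.24 with an estimated correlation). PSMB6 changed by 0.33. Immediate early genes were lower in 9 of 19 cases and higher in 3, 9 and 4 when adjusted over the list alone (-0.09 and 0.02 with library totals, adjusted p = 0.0329, adjusted p = 0.28 with an estimated correlation). DUSP1 changed by -0.99.

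Oxidative phosphorylation genes were higher in 12 of 42 cases and lower in 2, 26 and 0 with library totals (0.10, adjusted p = 0.0172, adjusted p = 0.29 with an estimated correlation and 0.0797 without Lo19S bortezomib replicate 1). The tricarboxylic acid cycle was higher in 7 of 17 cases and lower in 1, 13 and 1 with library totals (0.12, adjusted p = 0.0492, adjusted p = 0.19 with an estimated correlation). This call was lost with RLE factors (0.0662) and without control bortezomib replicate 2 (0.0575) or 3 (0.051) or Lo19S bortezomib replicate 1 (0.0854) or 3 (0.0529). Glycolysis genes were higher in 8 of 18 cases and lower in 3, 9 and 3 when adjusted over the list alone and 13 and 1 with library totals (0.12, adjusted p = 0.044, adjusted p = 0.27 with an estimated correlation), with HK1 at 0.49, a call lost with RLE factors (0.0646) and without control bortezomib replicate 3 (0.0516) or Lo19S bortezomib replicate 1 (0.073) or 2 (0.0617). Estrogen receptor targets were higher in 9 of 19 cases and lower in 4, 9 and 5 when adjusted over the list alone (median 0.07, mean -0.02, adjusted p = 0.104), and were called without control DMSO replicate 3 (0.036). NF-kappaB targets were lower in 7 of 15 cases and higher in 1, 7 and 2 over the list alone (-0.32, adjusted p = 0.0674), and were called without control bortezomib replicate 3 (0.0426).

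The largest rises in Lo19S cells under bortezomib were those of BLNK, a B-cell adaptor protein gene (log2 2.95, SE 0.257), MAP1A (2.60, SE 0.082), FSIP2 (2.20), ROM1 (2.19) and TMEM37 (2.04), and the largest falls those of the keratin genes KRT6A (-2.86, SE 0.090) and KRT81 (-2.55), CRYAB, IL1RL1 (-2.52) and CALCA (-2.50). HMOX1 (0.87, SE 0.053), DDIT3 (0.37, SE 0.039) and UCHL1 (1.07) were higher, and ATF4 (-0.25, SE 0.041), CDKN1A (-0.41, SE 0.042) and ZFAND2A (-1.25) were lower. FDX1 differed by -0.20 (adjusted p = 0.0632). The 19S particle was not called (6 of 17 higher and 2 lower, 13 and 0 with library totals, median 0.08, adjusted p = 0.107), nor were ATF4 targets (0.23), NRF2 targets (0.834), ubiquitin factors (0.79), mitosis (0.667) or autophagy genes (0.309). Further lists not called were assembly factors (0.23), mitochondrial ribosomal proteins (0.667), lipoylation genes (0.405), p53 targets (0.855), BCL2 family genes (0.0823), interferon-stimulated genes (0.667) and hypoxia genes (0.687).

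Under bortezomib 6349 genes differed between the states, 3230 higher (50.9%) and 3119 lower in Lo19S cells, with 334 and 260 at least 2-fold apart and a median SE of 0.095. Of the lists, 8 were called higher and 8 lower, and 6 of these calls held with an estimated correlation. Genes higher in the Lo19S state both under DMSO and under bortezomib numbered 957 (377.6 if independent) and genes lower in both 826 (404.4 if independent), and these comparisons share no library. With library totals the median of all genes was 0.115 (0.004 with TMM) and 72.3% of the calls were higher.

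The difference of the bortezomib responses, Lo19S minus control, was tested for each gene to ask where the states responded unequally. Heat shock genes responded less in Lo19S cells in 24 of 24 cases (median difference -0.57, camera adjusted p = 9.25e-35). BAG3 changed by -1.96 (SE 0.064), HSPA1A by -1.01 (SE 0.064), HSPA1B by -1.10 (SE 0.069) and DNAJB1 by -0.78 (SE 0.057). Proteasome genes rose less in Lo19S cells, in 15 of 17 cases and 16 when adjusted over the list alone for the 19S particle (-0.51, adjusted p = 6.35e-20), with ADRM1 at -0.90 and PSMD3 at -0.70, and in 12 of 13 cases and 13 over the list alone for the 20S core (-0.51, adjusted p = 1.39e-15), with PSMB4 at -0.77 and PSMB7 at -0.61. ADRM1 averaged 201.8 and 357.2 CPM in control and Lo19S cells with DMSO and 481.2 and 457.1 CPM with bortezomib. Mitosis genes fell less in 20 of 25 cases (0.52, adjusted p = 7.16e-15). PLK1 changed by 1.19 (SE 0.117) and CDK1 by 0.99 (SE 0.074). The tRNA synthetases rose more in 9 of 14 cases and less in 1, 10 and 1 over the list alone (0.21, adjusted p = 1.38e-05). AARS1 changed by 0.51 and HARS1 by -0.32.

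NRF2 targets differed downward in 10 of 19 cases and upward in 1 (-0.54, adjusted p = 6.07e-08), with AKR1C1 at -2.27 (SE 0.547), FTL, the ferritin light chain, at -1.45 and OSGIN1 at -0.91, while HMOX1 differed by -0.03 (adjusted p = 0.91). Under DMSO the 19S, NRF2 and mitosis lists had medians of 0.609, 0.469 and -0.435 in Lo19S against control cells. Under bortezomib these were 0.078, -0.02 and 0.089, and camera called none, so for these lists the medians of the states lay further apart under DMSO. With fry the 19S list was called under bortezomib (adjusted p = 0.00031). Heat shock medians went the other way, -0.139 under DMSO and -0.719 under bortezomib. Ubiquitin factors differed downward in 12 of 18 cases and upward in 1, 12 and 2 over the list alone (-0.37, adjusted p = 2.5e-09). ZFAND2A changed by -1.34 and UCHL1 by -1.18. Luminal markers differed upward in 10 of 18 cases and downward in 2, 10 and 3 over the list alone (0.30, adjusted p = 8.59e-07), with GATA3 at 1.28 and AGR2 at 1.01. Estrogen receptor targets differed upward in 8 of 19 cases and downward in 2, 9 and 2 over the list alone (0.20, adjusted p = 0.000868). PGR differed by 1.42 (SE 0.063), GREB1 by 1.42 and ESR1 by 0.71 (SE 0.080), so that each fell less in Lo19S cells. Ribosomal proteins differed downward in 37 of 42 cases, 40 over the list alone and 22 with library totals (-0.28, adjusted p = 2.01e-22). RPS2 changed by -0.45 and RPS19 by -0.39. Cholesterol genes differed downward in 9 of 21 cases and upward in 1 (-0.23, adjusted p = 0.00057), and fatty acid oxidation genes upward in 9 of 19 and downward in 1, 10 and 1 over the list alone (0.24, adjusted p = 0.0021), with CPT1A at 0.72.

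ATF4 targets differed upward in 11 of 20 cases and downward in 2, 12 and 2 over the list alone (0.27, adjusted p = 0.00353, adjusted p = 0.072 with an estimated correlation). STC2 changed by 0.70, PSAT1 by 0.57 and PPP1R15A by -1.25. DDIT3 differed by 0.25 (SE 0.088, adjusted p = 0.0283), a call lost without control DMSO replicate 2 (0.21), Lo19S DMSO replicate 3 (0.19) or Lo19S bortezomib replicate 1 (0.22), and ATF4 by -0.23 (SE 0.062), a call lost with library totals (-0.14). Mitochondrial-DNA-encoded genes differed downward in 10 of 13 cases, 11 over the list alone and 6 with library totals (-0.20, adjusted p = 2.88e-10, adjusted p = 0.059 with an estimated correlation). MT-CO1 changed by -0.36 and MT-CYB by -0.34. Basal markers differed downward in 4 of 10 cases and 5 over the list alone (-0.37, adjusted p = 0.0163, adjusted p = 0.10 with an estimated correlation). CD44 changed by -0.74. Autophagy genes differed downward in 8 of 23 cases and upward in 3, 9 and 3 over the list alone (-0.12, adjusted p = 0.0373, adjusted p = 0.072 with an estimated correlation), with GABARAPL1 at -1.03, a call lost without control DMSO replicate 1 (0.0521) or Lo19S DMSO replicate 2 (0.0599). With library totals the balance of its members turned, 6 differing upward and 5 downward (median -0.029). CDKN1A differed by -0.40 (SE 0.085) and FDX1 by -0.23 (adjusted p = 0.184).

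Among single genes the largest fitted upward differences were those of RBBP8NL and CCL28, which had 0 counts in control cells with bortezomib and differed at least 10.6-fold and 5.13-fold against 3 counts over that group, MYRFL (2.62, SE 0.658), DKK1, a secreted WNT inhibitor (2.16, SE 0.173), and NYNRIN (2.08, SE 0.788, adjusted p = 0.0429). MYRFL and NYNRIN had 3 counts in control cells with bortezomib, and the call of NYNRIN was lost without Lo19S DMSO replicate 2 (2.045) or 3 (2.05), control bortezomib replicate 1 (2.11) or 2 (1.504), or Lo19S bortezomib replicate 2 (1.94) or 3 (1.90). The largest downward differences were those of DUSP13 (-3.55, SE 0.592), KRT6A (-3.20, SE 1.015), C1orf116 (-2.96, SE 0.392), NAP1L2 (-2.89, SE 0.390) and C1S, a complement protease (-2.85, SE 0.554). KRT6A lost its call without Lo19S DMSO replicate 1 (-3.14) or 2 (-3.09).

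Lists not called for the difference were the unfolded protein response (adjusted p = 0.79), assembly factors (0.969), glutathione genes (0.283), the tricarboxylic acid cycle (0.129), lipoylation genes (0.194), mitochondrial ribosomal proteins (0.259) and glycolysis (0.877). The same held for replication (0.969), p53 targets (0.286), BCL2 family genes (0.465), NF-kappaB targets (0.408), interferon-stimulated genes (0.969), immediate early genes (0.947) and hypoxia genes (0.612). Oxidative phosphorylation genes (9 of 42 upward, 8 over the list alone, 0.126) were called without Lo19S bortezomib replicate 3 (0.0267).

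The difference of responses passed the test for 4094 genes, 2126 upward (51.9%) and 1968 downward, with 182 and 227 of them at least 2-fold and a median SE of 0.129. Of the lists, 6 were called upward and 10 downward, and 12 calls held with an estimated correlation. Across the 12541 genes called for the average response, the response in Lo19S cells was 0.827 times that in control cells (jackknife SE 0.0393), and 97.9% of them moved in the same direction in both states. Of all 12541, 8754 (69.8%) had a smaller and 3787 a larger response in Lo19S cells. Among the 3781 of these genes whose responses differed, 3241 responded less and 540 more in Lo19S cells. With library totals the median of all genes was 0.104 (0.01 with TMM) and 72.6% of the calls were upward.

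**Figure D3:**
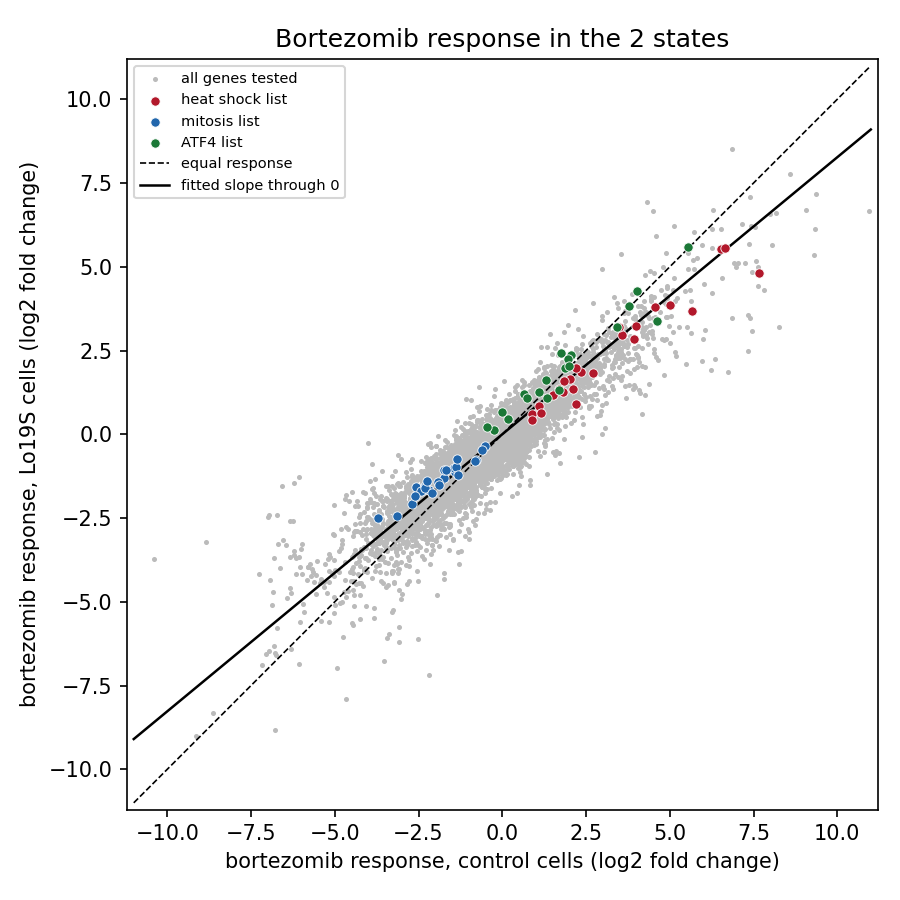
Log2 fold change with bortezomib in Lo19S cells against that in control cells, 1 point per gene, with heat shock, mitosis and ATF4 list members coloured, a dashed line of equal response and a solid line of slope 0.827. Heat shock genes lie on the side of a smaller response in Lo19S cells, 24 of 24, and fitted values of genes at 0 counts in a group depend on the prior count.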

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

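The tests of 1 common factor and of RNA from bortezomib-treated cells, the GC offsets, the thinning and the rule that a list's 95% order-statistic interval must lie clear of the value an explanation needs were chosen after the results were seen. The list medians and gene values listed first here are differences of the log2 bortezomib response, Lo19S minus control, that passed the test of the difference itself. Each is listed because the states responded unequally. Later paragraphs of this section also give values of other comparisons. The difference passed for 4094 genes. Of the 100 splits of the libraries that were compared, 1, the real one, gave as many genes, and the highest other gave 3817. The 10 splits that part the states under bortezomib alone reached 3817 genes, the 9 that part them under DMSO alone reached 341, and the 80 that mix both reached 0. These other splits hold the effect of the state itself, in the contrast or in the spread within groups, so they do not exclude chance for the difference of responses.

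The list medians were -0.512 for the 19S particle, -0.514 for the 20S core, -0.368 for ubiquitin factors, -0.571 for heat shock genes, -0.541 for NRF2 targets, -0.201 for mitochondrial-DNA-encoded genes, -0.231 for cholesterol synthesis, -0.371 for basal markers, -0.122 for autophagy and -0.281 for ribosomal proteins. They were 0.268 for ATF4 targets, 0.212 for tRNA synthetases, 0.243 for fatty acid oxidation, 0.2 for estrogen receptor targets, 0.302 for luminal markers and 0.516 for mitosis. With an estimated correlation the calls of mitochondrial-DNA-encoded genes (adjusted p = 0.059), basal markers (adjusted p = 0.10), autophagy (adjusted p = 0.072) and ATF4 targets (adjusted p = 0.072) were lost.

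Of the panel, PSMD2 differed by -0.353, HSPA1A by -1.01, HSPA1B by -1.101, DNAJB1 by -0.775, DDIT3 by 0.249, ATF4 by -0.231, ESR1 by 0.708, PGR by 1.419 and CDKN1A by -0.403. The genes with the largest fitted differences were RBBP8NL (6.69), CCL28 (5.658), MYRFL (2.619), DKK1 (2.162) and NYNRIN (2.076) upward and DUSP13 (-3.553), KRT6A (-3.204), C1orf116 (-2.959), NAP1L2 (-2.888) and C1S (-2.847) downward. Fitted values of RBBP8NL and CCL28 depend on the prior count, since control cells with bortezomib had 0 counts of either. DDIT3 lost its call without control DMSO replicate 2 (0.21), Lo19S DMSO replicate 3 (0.19) or Lo19S bortezomib replicate 1 (0.22), and KRT6A without Lo19S DMSO replicate 1 (-3.14) or 2 (-3.09). NYNRIN lost its call without Lo19S DMSO replicate 2 (2.045) or 3 (2.05), control bortezomib replicate 1 (2.11) or 2 (1.504), or Lo19S bortezomib replicate 2 (1.94) or 3 (1.90). Of list members, CRYAB differed by -2.821, BAG3 by -1.959, ZFAND2A by -1.338, UCHL1 by -1.179, AKR1C1 by -2.269, FTL by -1.447, ADRM1 by -0.902, PSMD3 by -0.695, PSMB4 by -0.768 and PSMB7 by -0.613. RPS2 differed by -0.451, RPS19 by -0.391, MT-CO1 by -0.361, MT-CYB by -0.337, PLK1 by 1.191 and CDK1 by 0.989.

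Heat shock genes responded less to bortezomib in Lo19S cells. Scaling set by a few abundant genes is argued against, since the least negative median under 3 other scalings was -0.477 (-0.917 to -0.26), and so is unequal depth, since the median after thinning was -0.576 (-0.992 to -0.363). That 1 common factor scales down every bortezomib-responsive gene is argued against by the ATF4 list. In it 11 members called singly differed upward, Lo19S minus control, and 2 downward. The list's own call was lost with an estimated correlation (adjusted p = 0.072). These differences are signed, and 2 of the 20 members fell in control cells, so an upward difference is not always a larger change. The list's median, Lo19S against control, was -0.14 under DMSO and 0.101 under bortezomib, so the starting level enters these differences. Of the genes called for the average response, 3781 also differed in response, 3241 responding less and 540 more in Lo19S cells. Across all 12541 genes called for the average response, the ratio of Lo19S to control responses was 0.827. Heat shock medians were 2.28 in control and 1.85 in Lo19S cells, and a reduction beyond that ratio was not tested. A weaker heat shock response of the Lo19S state, whether or not particular to these genes, may be a hypothesis, found and tested on the same data. The knockdown and the earlier doxycycline stay open as its source, since both went with the state.

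Proteasome genes were higher and mitosis genes lower in Lo19S cells under DMSO. GC content bias of control DMSO replicate 3 is argued against, since without it the 20S median was 0.604 (0.58 to 0.784) and the mitosis median -0.495 (-0.522 to -0.404). GC content bias of all libraries is argued against too, since with GC offsets the medians were 0.611 (0.515 to 0.803) and -0.425 (-0.449 to -0.405). The effects of doxycycline itself and of the knockdown cannot be told apart, because 0 groups received doxycycline without the Lo19S state.

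Control DMSO replicate 3 stood apart from the other replicates of its group. Its deviation from them went with the GC content of transcripts, with a Spearman rho across 6315 genes of 0.77, and genes are not independent replicates. The highest absolute rho of another library was 0.653, in its own group, where deviations mirror each other by construction. A GC bias of library preparation or sequencing is consistent with that rho. RNA of bortezomib-treated cells in that library is argued against, since the median ratio of the 20 genes most raised by bortezomib to their level in its replicates was 1.027.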

How the results depend on the processing

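GC offsets and thinning were chosen after the results were seen, and GC offsets also remove biology that follows GC. All 5 counts of called genes lay within 1.5 times their value under every alternative tried, from 2840 to 4603 for Lo19S against control under DMSO when 1 library was left out, 11659 to 12124 and 10872 to 11828 for bortezomib in control and Lo19S cells, 5368 to 7080 for the states under bortezomib and 3408 to 4981 for the difference of responses. The replicate number as a block gave 3445, 11922, 11349, 6196 and 3889 genes in that order, and DESeq2 gave 2626, 11437, 10764, 5390 and 3213. The response ratio ran from 0.811 to 0.853 without 1 library and was 0.829 with the block. A fit of only the groups compared gives no value for the difference of responses. Of 15368 alternative values of named genes, 14973 kept their side of the threshold and, but for 19 that were not called, their direction, 384 lost their call, 8 gained one and 3 turned. Those were IDH3A with library totals (-0.049, bortezomib in control cells) and, with GC offsets, VARS1 (0.314) and TKT (0.062) in Lo19S cells with bortezomib; the cause was not tested. Of 2635 alternative values of lists, 2517 stayed, 62 lost their call, 34 of them with an estimated correlation, 56 gained one and 0 turned. The number of lists called moved to 13 for bortezomib in control cells, 12 for Lo19S cells and 6 for the states under bortezomib with an estimated correlation. With fry, which compares a list with no other genes, it was 21, 31, 29, 27 and 25 in the order of the comparisons above; the cause was not tested further. Depth limited calls: thinned to the smallest library, 3207, 11339, 10808, 5755 and 3501 genes were called.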

Other observations

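The lists of SRF and YAP targets and of squamous, histone, zinc finger and immunoproteasome genes, and the test of a mild bortezomib response, were chosen after results were seen. Counts of replication-dependent histone genes fell with bortezomib, 12 of 15 in control cells (median -1.461, adjusted p = 0.00874, adjusted p = 0.0546 with an estimated correlation). In Lo19S cells 13 of 15 fell and 1 rose (median -1.14, adjusted p = 0.00218, adjusted p = 0.0279 with an estimated correlation). The polyA kit selects polyadenylated RNA, so histone RNA without a polyA tail is not measured here, and only the 15 genes that passed the filter are covered. Of 427 zinc finger genes, 223 rose and 103 fell with bortezomib in control cells (median 0.324, adjusted p = 0.00874, adjusted p = 0.143 with an estimated correlation). In Lo19S cells 204 rose and 105 fell (median 0.223, adjusted p = 0.068). Under bortezomib 42 were higher and 129 lower in Lo19S cells (median -0.112, adjusted p = 0.0104, adjusted p = 0.228 with an estimated correlation). The responses differed upward for 21 and downward for 77 (median -0.129, adjusted p = 0.0237, adjusted p = 0.335 with an estimated correlation). Across 14439 genes, bortezomib log2 fold changes went with lower GC content of transcripts (Spearman rho -0.218 in control and -0.28 in Lo19S cells). That rho was 0.041 for Lo19S against control under DMSO. Whether this trend accounts for the shifts of the histone or zinc finger genes was not tested. PSMB9, which prompted the immunoproteasome list, fell by 4.08 in control cells. The 4 other measured members fell too (median -0.73) but as a list were not called (adjusted p = 0.0748).

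Genes led by CNN1, CCN2 and ACTA2 were the most lowered in Lo19S cells under DMSO, and lower activity of SRF and YAP target genes as a set was tested as a hypothesis. Of the 24 targets that had not prompted the list 19 fell (median -0.294, -0.494 to -0.212, adjusted p = 7.39e-16, adjusted p = 0.026 with an estimated correlation). Lower SRF and YAP activity may thus go with the Lo19S state. Under bortezomib 16 of the same 24 were lower and 3 higher (median -0.417, adjusted p = 2.2e-06, adjusted p = 0.228 with an estimated correlation).

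KRT6A and SCEL were among the genes most raised by bortezomib in control cells, and a rise of squamous differentiation genes as a set was tested. Of the 16 measured genes that had not prompted the list 7 rose and 9 fell (median -0.9, -1.816 to 3.159, adjusted p = 0.994), which leaves the question open.

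Across genes, the Lo19S and bortezomib log2 fold changes under these DMSO controls went together more often than apart. Of genes called in both comparisons, 965 were higher in both (673.43 if independent) and 1132 lower in both (805.91 if independent). Another 549 were higher in Lo19S cells and lower with bortezomib (726.51 if independent), and 579 the other way (747.04 if independent). Both comparisons share the control DMSO libraries, which adds to such overlap, and their covariance exceeded the one simulated for shared libraries alone by 0.118 (0.139 against 0.0213, SD 0.00166, 20 simulations). The correlation across genes, 0.261, lay below the simulated 0.477, a measure that is high by construction where shared noise is the only source of change. The shared libraries alone are thus argued against as the source, although part of the overlap may come from them. A mild form of the bortezomib response in Lo19S cells, its heat shock part included, needs a rise of heat shock genes under DMSO. No such rise was called: 13 of 24 fell and 2 rose (median -0.139, -0.219 to -0.017). The interval treats genes as independent, and the list's downward call was lost with an estimated correlation (camera adjusted p = 0.20). The values thus show no rise of this list and establish no fall.

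For each of the comparisons of 3 with 3 libraries, the real split was 1 of 10, too few for a share under 0.05. The real splits gave 3628, 11976, 11408 and 6349 genes and the highest of the others 0. Each other split mixes the compared groups, so the effect itself widens the spread within groups, and the 0 is no clean null.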
